A study of Mus musculus with 7 samples.

How the data were processed

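Single-cell RNA of mouse liver was measured in 7 libraries: control replicates 1 to 3, ConA 72 h replicates 1 and 2, and ConA 96 h replicates 1 and 2. Per the labels, livers were digested with 0.075% collagenase, strained at 70 µm, layered on a 40 and 70% Percoll gradient and loaded for 8000 target cells on 10x 3' v3.1 chips. The authors ran Cell Ranger against mm10 and named Seurat for later steps, without versions; the deposited files are the filtered matrices, 1 per library, and their values were checked to be whole-number UMI counts over 32285 genes. Totals ran from 35507487 to 132027044 UMIs per library, and the lowest barcode of each library held 500 or 501 UMIs. Gene positions come from the mouse annotation of build mm10 (GENCODE), matched by gene ID for 32158 genes.

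Barcodes with under 300 detected genes or over 15% mitochondrial UMIs were left out. Doublet scores came from simulated doublets (Scrublet method). Its automatic threshold marked at most 0.0398% in 5 of the 7 libraries, so the barcodes with the top scores were removed at a rate of 0.8% per 1000 barcodes, 4191 in all, a rule set after the data were seen. The counts were scaled to 10000 per cell and logged, and 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (seed 1) gave 33 clusters, of which 3 were split further into 53 in all. Clusters were named from markers of 20 cell classes, by the class with the most markers among the cluster's 10 leading genes and then by the mean fold of its markers over the other clusters. A name needed at least 3 detected markers and a mean fold of at least 0.5 (log2). A cluster with no marker among its leading genes was named by the highest mean fold if at least 10 markers of that class were detected, the next class lay at least 0.5 (log2) lower and its UMI count was not low. In this way 4 clusters were named hepatocyte-like, and 8 clusters stayed unnamed. The thresholds of this rule were not among the choices fixed beforehand. Markers, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The monocyte-derived class joins classical monocyte-like and monocyte-derived macrophage-like clusters. Clusters were named without regard to group. The change of a gene that also names a cluster is not independent of the naming.

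Control replicates 1 and 3 shared 6080 barcodes. The median chi-square of their gene totals was 0.514, close to the 0.455 of counting noise, against 9.10 to 149 for other pairs. Some genes differed by more than counting noise: the chi-square per degree of freedom was 10.4, against 192 to 4228 for other pairs, and 83.1% of genes lay under the 95% point. Of the 5124 retained shared cells 99.9% received the same class. Their counts were averaged into 1 control capture, which leaves 2 control captures and 6 units in each test where 7 libraries had been planned.

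UMIs were summed per unit and class (at least 20 cells) and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) at a Benjamini-Hochberg adjusted p of 0.05. For Kupffer-like and monocyte-derived cells the 3 groups were fitted together; for the other classes both ConA times were compared with control. The SE is the size of the log2 change over the root of F. The units held 607463 to 6774583 UMIs in Kupffer-like cells, 483177 to 54686543 in monocyte-derived, 410275 to 16236978 in endothelial-like, 636623 to 7736798 in T-like, 233325 to 1844556 in NK or ILC1-like and 307239 to 2210495 in B-like cells. Data were simulated with 1 common dispersion for all genes of a class and without an effect of replicate number. There edgeR recovered 62.2% of changes of 2 (log2) in Kupffer-like cells, 64.3% in monocyte-derived, 91.6% in endothelial-like and 91.5% in T-like cells. It recovered 5.05%, 4.12%, 21.9% and 32.6% of changes of 1, and 2.70% to 5.65% of its calls were false. These rates hold for that setting alone. Levels are TMM-normalised counts scaled to a common library size (CPM). A gene with 1 to 3 control UMIs is given as a ratio with its 95% counting interval (exact binomial). One with 0 is given as a lower bound from a floor of 3 counts over the group. Both pool the UMIs of a group, so the library with the most UMIs weighs most, and both cover counting error alone.

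Named genes are the 8 largest rises and 8 largest falls of each macrophage comparison with control (4 and 4 elsewhere) among those with an adjusted p under 0.05, an average log2 CPM of at least 5 and no overlap between the libraries of the groups. Every library of one group then lies beyond every library of the other. Predicted genes, mitochondrial, haemoglobin, antigen receptor, sex-linked and other-cell genes are left out of the picks. Up to 4 members of each list with the smallest p are added. Some genes that this rule names are not reported here. The 28 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison; of 145 tests 83 passed by the preset correlation and 1 by the estimated one. Members were also counted when adjusted over the list alone. The macrophage classes had 20 lists (no stellate list in monocyte-derived cells), and the others the interferon, MHC class II and cell cycle lists with their own. The T cell transcript list had too few tested members in the macrophage classes, and the stellate activation and quiescence lists have no planned test. Hp stands in both the monocyte and the iron list, and Mmp9 in both the neutrophil and the matrix list.

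Shares of cells were compared with an exact permutation test, two-sided, over the 15 splits of 2 captures against 4 ConA libraries (35 splits of 3 against 4 had been planned), adjusted over 18 classes for shares of all cells, 11 for leukocytes and 4 for monocytes and macrophages. After removal of the group means, shared replicate numbers correlated at 0.116 or more in Kupffer-like, monocyte-derived, T-like and hepatocyte-like cells. Fits with replicate number as a block therefore stand beside those results. Alternatives fixed beforehand were DESeq2 1.42.0, no low-count filter, a stricter cell filter (500 genes, 10% mitochondrial), doublets kept, Leiden resolution 2, at least 50 cells, the replicate block, macrophage-like clusters alone, other denominators of shares, and each library left out. Alternatives chosen after seeing the data were control replicates 1 and 3 as separate libraries, control replicate 2 as the sole control library, the Kupffer-like cluster of full UMI count, classical monocyte clusters alone and at least 10 cells. Too few units reached 20 cells for the planned test of neutrophil-like cells (none in control) and stellate-like cells (1 control capture and 1 ConA library). Leaving out control replicate 1 or 3 keeps the other file of the same capture, so neither setting removes that capture. Groups of 2 are too small for a test of outliers. R 4.3.3, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.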

Results

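The series asked how macrophages differ between healthy and diseased mouse livers. RNA of single cells was captured with 10x 3' chemistry from untreated control livers (3 libraries) and from livers 72 h (2 libraries) or 96 h (2 libraries) after ConA. ConA is the usual short name of concanavalin A, a plant lectin that activates T cells and injures the liver. Livers were digested with collagenase and the cells were passed over a Percoll density gradient. Control replicates 1, 2 and 3 held 38364331, 44103836 and 35507487 unique molecular identifiers (UMIs), the 72 h replicates 1 and 2 held 101213404 and 65582443, and the 96 h replicates 1 and 2 held 132027044 and 48938587. The median per barcode was 2480, 2645.5 and 2385 UMIs in control, 9696 and 3890 at 72 h, and 8083 and 5101.5 at 96 h. After filtering, 51256 of 61325 barcodes remained and were grouped into 53 clusters, which were named by markers fixed before the data were examined.

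Control replicates 1 and 3 shared 6080 barcodes, 96.1% of the smaller set. Over those barcodes, which are not independent replicates, the UMI counts correlated at r = 0.999. Every other pair of libraries shared 7 to 32 barcodes. They were therefore averaged and counted as 1 control capture, so that control holds 2 captures and each ConA time 2 libraries. The labels do not say whether the libraries come from separate animals, so the p-values measure only the spread between these samples. Libraries also differed by replicate number. Hepatocyte-like cells made up 55.4% and 95.2% of cells in control replicates 1 and 2, 3.72% and 86.4% in the 72 h replicates, and 5.90% and 79.0% in the 96 h replicates. Haemoglobin took 39.9% of the UMIs of the 96 h replicate 2 and 0.180% to 1.58% in the other libraries.

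Monocyte-derived cells, the circulating monocytes and the macrophages that arise from them, made up a larger part of the leukocytes after ConA, and Kupffer-like cells, the resident macrophages of the liver sinusoids, a smaller part. Kupffer-like cells were 34.9% ± 19.4 of leukocytes in control (SD, n = 2) and 9.42% ± 0.785 in ConA (SD, n = 4). Monocyte-derived cells were 6.86% ± 3.93 of leukocytes in control and 33.7% ± 9.64 in ConA. Neutrophil-like cells were 2.71% ± 1.63 in control and 16.1% ± 3.40 in ConA, B-like cells 15.98% ± 8.78 and 5.91% ± 1.43, and plasmacytoid dendritic-like cells 7.92% ± 2.45 and 2.72% ± 1.04. For each of these 5 classes every ConA library lay on the same side of both control captures. The exact permutation test (two-sided) gave p = 0.0667, the smallest p that the 15 splits allow, and the adjusted p was 0.147 for the Kupffer-like class. T-like cells were 17.1% ± 2.21 and 16.5% ± 1.41 (exact p = 0.667) and NK or ILC1-like cells 7.58% ± 0.189 and 4.56% ± 1.34 (exact p = 0.133). Conventional dendritic-like cells were 6.28% ± 0.699 and 9.27% ± 2.44 (exact p = 0.133). Within replicate number 1 the Kupffer-like share of leukocytes was lower in ConA by 39.4 points and within number 2 by 11.7 points, and the monocyte-derived share was higher by 37.9 and 15.7 points. Among monocytes and macrophages alone, Kupffer-like cells were 80.5% ± 16.6 in control and 22.7% ± 5.41 in ConA (exact p = 0.0667, adjusted p = 0.0889). Of all cells, Kupffer-like cells were 5.68% ± 6.99 and 4.12% ± 3.71 (exact p = 0.6) and monocyte-derived cells 0.612% ± 0.395 and 17.8% ± 17.7 (exact p = 0.133). This measure also depends on the hepatocyte-like share. No share passed the test. The gradient, the UMI depth and the filter on detected genes can each set such shares.

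**Figure D1:**
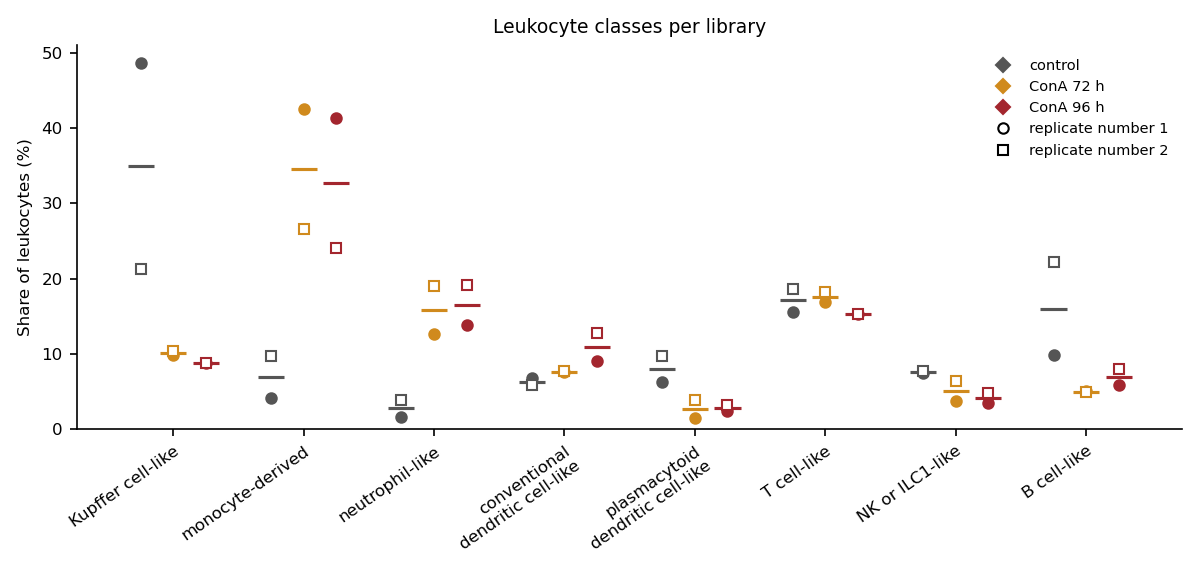
Share of leukocytes (%, vertical axis) of 8 cell classes (horizontal axis) in each library, with circles for replicate number 1, open squares for replicate number 2 and horizontal lines for the mean of a group; control replicates 1 and 3 are 1 point. Kupffer-like cells lie at 48.7% and 21.2% in control and at 8.74% to 10.4% in ConA, while T-like cells overlap between the groups.

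Kupffer-like cells at 72 h were compared with control to learn how the resident macrophages stand after the injury. They carried more transcripts of genes of cell division and fewer of genes that interferon induces. Ccl8, a chemokine that attracts monocytes (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, mm10), rose by a log2 change of 5.84 (SE 0.34, adjusted p = 0.00214). Its level, in normalised counts (CPM), was 1.14 ± 0.0165 in control and 66.9 ± 5.21 at 72 h (SD, n = 2 each). The control level rests on few UMIs, 0.0130 and 0.0152 per cell over 578 and 66 cells, so its SD does not cover counting error. Alcam, an adhesion molecule, rose by 3.70 (SE 0.30, adjusted p = 0.00787). Marco, a scavenger receptor for bacteria and a marker of the class, rose by 2.61 (SE 0.26, adjusted p = 0.0177), from 272 ± 80.4 to 1657 ± 161 CPM. Of 20 cell cycle genes tested, 7 rose over all genes and 15 rose when adjusted over the list alone, with a median log2 change of 3.03 (camera, adjusted p = 5.48e-46; adjusted p = 0.163 with an estimated correlation). Among them were Ube2c, which marks mitotic proteins for breakdown (4.56), Birc5, a part of the complex that corrects chromosome attachment (4.26), Stmn1, a regulator of microtubules (3.36), and Mki67, a marker of dividing cells (2.68). Pclaf, a partner of the replication clamp, and Cenpe, a motor protein of the kinetochore, rose by 3.41 and 2.89. In the same ConA libraries B-like cells, which form 1 cluster here, held 2.70 to 9.13 UMIs of the cell cycle list per cell, against 7.24 to 18.6 in Kupffer-like cells and 5.99 and 6.58 in Kupffer-like cells of control. Of 22 interferon response genes, 2 fell and 9 fell when adjusted over the list alone, with a median of -0.83 (camera, adjusted p = 3.43e-11; adjusted p = 0.163 with an estimated correlation). Irf7, a transcription factor of the interferon response, fell by 1.67, and Rsad2, the antiviral protein viperin, by 1.40. Outside the list, Oasl1 (ENSMUSG00000041827, chromosome 5, 114923240 to 114937915) fell by 1.85 (SE 0.19, adjusted p = 0.0177), and Oas2 and Oas3 fell by 1.98 and 2.07. These belong to the oligoadenylate synthetase family, whose members share similar sequence. Slfn5 (-1.73) and Siglec1 (-1.70), both induced by interferon, fell as well.

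Other lists moved by the preset test at 72 h, each without a call by the estimated correlation. Lipid-associated macrophage genes had a median of 1.17, with 8 members that rose and 1 that fell when adjusted over the list alone (camera, adjusted p = 8.27e-07; adjusted p = 0.266 with an estimated correlation). Spp1, the secreted matrix protein osteopontin, was at 47.6 ± 28.5 CPM against 8.22 ± 1.08 in control (2.70, adjusted p = 0.0571). This was at most 0.653 UMIs per Kupffer-like cell in a 72 h library, against at most 0.209 in T-like and 1.40 in hepatocyte-like cells, so that it is not told apart from free RNA. T-like cells of the 4 ConA libraries held 0.122 to 0.819 of the rise per Kupffer-like cell for Fabp5, a fatty acid carrier of that list. For Lgals3, a galectin of that list, they held 0.0805 to 0.295. At the highest they held 0.172 for Trem2, 0.151 for Cd63, 0.326 for Ctsd, 0.338 for Mmp12 and 0.473 for Gpnmb. They reached 1.24 for Cd9, 1.84 for Ctsl, 3.13 for Pld3 and 35.3 for Itgax. For Itgax, T-like cells of these libraries held 0.101 to 0.291 UMIs per cell and Kupffer-like cells 0 to 0.0558. Its T-like level is thus above all that Kupffer-like droplets held, and its ratio does not gauge free RNA. In control replicate 1, T-like cells held 0.810 Fabp5 UMIs per cell and Kupffer-like cells 0.421. The Fabp5 ratios are therefore upper limits of free RNA. Apoe, Lpl, Cd36 and Ctsb did not rise per cell in each library. A part from free RNA is thus open for this list at both times, and was not tested for monocyte genes. Monocyte genes had a median of 1.73 (adjusted p = 2.68e-05; adjusted p = 0.163 with an estimated correlation). Genes of the early stress response to tissue handling had a median of -1.28, with 11 members lower when adjusted over the list alone (adjusted p = 9.42e-10; adjusted p = 0.355 with an estimated correlation). Apoptotic-cell uptake (-0.34; 0.000733), inflammatory cytokines and mediators (-0.63; 0.00537), MHC class II presentation (-0.56; 0.0167) and Kupffer identity (-0.39; 0.0280) had lower medians, with the preset adjusted p second; cholesterol synthesis (0.54; 0.0175) had a higher one. For these 5 lists, in that order, adjusted p = 0.163, 0.487, 0.355, 0.266 and 0.487 with an estimated correlation. Transcripts of other cells were also higher. Those of neutrophils had a median of 2.33 (adjusted p = 0.0280; adjusted p = 0.437 with an estimated correlation), with S100a8, a neutrophil calcium-binding protein, at 3.15 (adjusted p = 0.0816). Those of hepatocytes had a median of 0.48 (adjusted p = 0.0234; adjusted p = 0.667 with an estimated correlation), with Cps1, an enzyme of the urea cycle, at 2.57 (adjusted p = 0.0681). Lists that did not pass were alternative activation (median -0.22, mean 0.03, preset adjusted p = 0.788), matrix remodelling enzymes (0.16, 0.277), iron and haem handling (0.36, 0.156) and glycolysis (0.36, 0.0616). Nor did B cell transcripts (1.34, 0.572), endothelial transcripts (-0.77, 0.142), stellate transcripts (0.65, 0.378) or peritoneal macrophage genes (0.04, 0.568) pass. With replicate number as a block, iron and haem handling (0.38, preset adjusted p = 0.0322), glycolysis (0.37, 0.044) and endothelial transcripts (-0.91, 0.044) passed too.

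Of 11417 genes tested in Kupffer-like cells at 72 h, 37 changed (28 rose, 9 fell; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). DESeq2 called 195 (124 rose, 71 fell), and edgeR 240 with replicate number as a block (143 rose, 97 fell, all 37 among them). The calls rest on few libraries: the count was 9 without control replicate 2, 5 without the 72 h replicate 1, 5 without the 96 h replicate 1 and 61 without the 72 h replicate 2. Of the 16 genes named here that passed, 7, 3, 4 and 13 kept their call without those libraries, and 13, 14 and 14 without control replicate 1, control replicate 3 and the 96 h replicate 2. The lists for interferon response, cell cycle, lipid-associated genes, monocyte genes, uptake and early stress kept their calls without any 1 library. Without control replicate 1 or 3, the other file of that capture stays in the test. Kupffer identity lost its call without control replicate 1 (-0.31), the 72 h replicate 1 (-0.36) and the 72 h replicate 2 (-0.46), and neutrophil transcripts without control replicate 2 (2.26) and the 72 h replicate 1 (1.56). The inflammatory list (0.0505) and MHC class II (-0.44) lost theirs without the 72 h replicate 1, and cholesterol synthesis (0.14) and hepatocyte transcripts (-0.65) without the 72 h replicate 2. Hepatocyte transcripts also had a median under 0 with the strict cell filter (-0.998), in the cluster of full UMI count (-0.43) and with control replicate 2 as the sole control library (-0.22). With the strict cell filter 22 genes changed, with doublets kept 142 and at Leiden resolution 2, 149. The class joins a cluster of high UMI count (453 and 41 cells in control replicates 1 and 2, 295 and 24 at 72 h, 452 and 16 at 96 h) with a cluster of low UMI count. The latter held 127 and 25, 296 and 56, and 287 and 26 cells.

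At 96 h Kupffer-like cells again carried more of Ccl8 and of cell cycle genes than control and fewer interferon response genes. Ccl8 rose by a log2 change of 4.87 (SE 0.35, adjusted p = 0.00964), to 35.1 CPM. Spp1 rose by 4.56 (SE 0.43, adjusted p = 0.0242), from 8.22 ± 1.08 to 185.5 ± 2.55 CPM (SD, n = 2 each; ENSMUSG00000029304, chromosome 5, 104435118 to 104441050). Per cell, Kupffer-like cells held 1.67 and 2.55 Spp1 UMIs in the 96 h replicates 1 and 2, T-like cells 0.337 and 0.110 and hepatocyte-like cells 1.07 and 2.16, so a part from free RNA is open. The same holds for S100a8, at 1.80 and 1.41 UMIs per Kupffer-like cell and 0.871 and 0.0822 per T-like cell. Alcam rose by 3.67 (SE 0.30, adjusted p = 0.0125) and Stmn1 by 2.45 (SE 0.25, adjusted p = 0.0269), while Oasl1 fell by 1.61 (SE 0.19, adjusted p = 0.0381). S100a8, a neutrophil transcript, rose by 4.81 (SE 0.57, adjusted p = 0.0381). Neutrophil transcripts had a median of 4.04, with 1 member that rose and 5 when adjusted over the list alone (camera, adjusted p = 1.24e-08; adjusted p = 0.113 with an estimated correlation). In the cell cycle list 1 gene rose and 12 rose when adjusted over the list alone (median 2.30, adjusted p = 4.45e-25; adjusted p = 0.113 with an estimated correlation). Of the 22 interferon response genes 0 fell and 8 fell when adjusted over the list alone (median -0.83, adjusted p = 3.05e-09; adjusted p = 0.114 with an estimated correlation). Lipid-associated macrophage genes had a median of 1.35, with 1 member that rose and 10 when adjusted over the list alone (adjusted p = 4.4e-13; adjusted p = 0.113 with an estimated correlation). Marco was higher by 1.93 (adjusted p = 0.0603), Hmox1, which breaks down haem, by 1.36 (adjusted p = 0.123), and Cps1 by 3.05 (adjusted p = 0.0784).

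In Kupffer-like cells at 96 h, monocyte genes (median 2.08, preset adjusted p = 3.44e-07), iron and haem handling (0.74, 0.000255), glycolysis (0.60, 0.000375), hepatocyte transcripts (0.71, 2.79e-05) and stellate transcripts (2.35, 0.00196) were higher by the preset test. Genes of early stress (-1.03, 4.92e-10), inflammatory mediators (-0.73, 0.000685) and MHC class II (-0.46, 0.00989) were lower. For these 8 lists, in that order, adjusted p = 0.113, 0.113, 0.251, 0.429, 0.251, 0.251, 0.388 and 0.251 with an estimated correlation. Kupffer identity (-0.21, preset adjusted p = 0.469), uptake (-0.18, 0.105), alternative activation (-0.05, 0.716), matrix enzymes (0.34, 0.065) and cholesterol synthesis (0.16, 0.419) did not pass. Nor did B cell (1.37, 0.716) and endothelial (0.19, 0.884) transcripts or peritoneal genes (0.01, 0.57). Of 11417 genes, 10 changed (9 rose, 1 fell; edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 137 (104 rose, 33 fell), and edgeR 178 with replicate number as a block (124 rose, 54 fell, all 10 among them). The count in edgeR was 0 without control replicate 2 (1059 genes at an unadjusted p under 0.05, against 1211 with all libraries), 0 without the 96 h replicate 1 (927 at an unadjusted p under 0.05), 3 without the 96 h replicate 2 and 57 without the 72 h replicate 2. Of the 6 genes named as passing, 0, 0, 2 and 6 kept their call without those libraries, and 5, 6 and 5 without control replicates 1 and 3 and the 72 h replicate 1. Without the 96 h replicate 1 the inflammatory list (-0.10) and glycolysis (0.36) lost their calls, without the 96 h replicate 2 MHC class II (-0.21), and stellate transcripts without control replicate 2 (-0.12) and the 72 h replicate 2 (0.35). Stellate transcripts also had a median under 0 in the cluster of full UMI count (-0.10) and with control replicates 1 and 3 as separate libraries (-0.0687). Hepatocyte transcripts had one with the strict cell filter (-0.74), with doublets kept (-0.57), at Leiden resolution 2 (-0.64) and in the cluster of full UMI count (-0.46). The count of changed genes was 1 with the strict cell filter, 3 with at least 50 cells, 61 with doublets kept and 57 at resolution 2.

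Between 96 h and 72 h, cell cycle genes took a smaller part of the UMIs of Kupffer-like cells at the later time (0.0790% and 0.129% against 0.182% and 0.160%). Per cell the 96 h replicate 2 held more (18.6 UMIs against 14.74 in the 72 h replicate 2), with 14460 UMIs per cell against 9213, and the 96 h replicate 1 fewer (7.24 against 16.44). The list had a median log2 difference in CPM of -0.80 (camera, adjusted p = 9.21e-15; adjusted p = 0.327 with an estimated correlation), and it kept its call without any 1 library. Stmn1 was at 123 CPM at 96 h and 229.9 CPM at 72 h (-0.91, adjusted p = 1), and Spp1 at 185.5 and 47.6 CPM (1.86, adjusted p = 1). No gene changed in edgeR (0 calls, 264 at an unadjusted p under 0.05) or in DESeq2 (0 calls). Neutrophil transcripts were higher at 96 h by a median of 1.44 (adjusted p = 9.08e-09; adjusted p = 0.265 with an estimated correlation), the other list that kept its call without any 1 library.

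**Figure D2:**
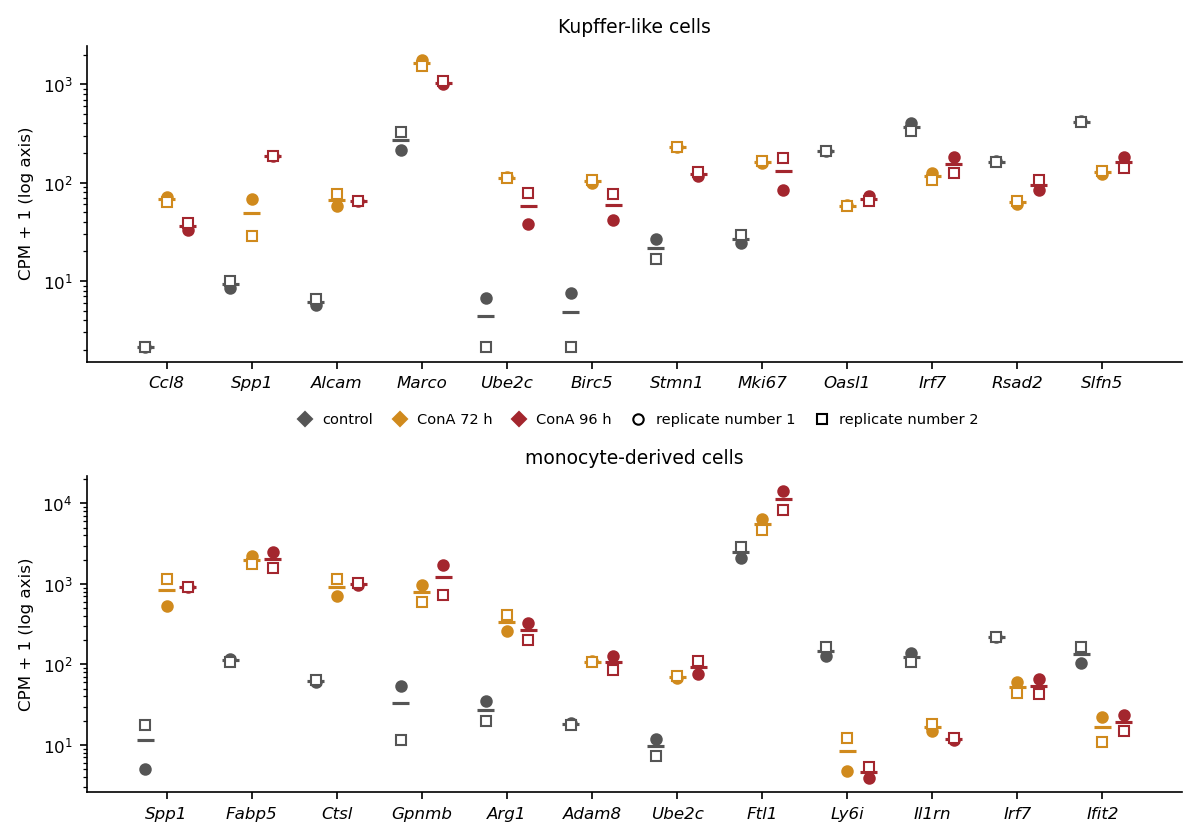
Level (CPM + 1, logarithmic vertical axis) of 12 genes in Kupffer-like cells (top) and 12 in monocyte-derived cells (bottom) in each library, with circles for replicate number 1, open squares for number 2 and lines for group means. In Kupffer-like cells Ccl8 lies at 1.14 CPM in control and at 66.9 CPM at 72 h; Oasl1 lies at 209 CPM in control and at 57.6 CPM at 72 h.

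Monocyte-derived cells at 72 h were compared with control to learn how these cells differ from the few found in control. They carried more transcripts of lipid-associated macrophage genes and fewer of interferon response genes. Fabp5, a fatty acid carrier (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607), rose from 112 ± 7.21 CPM to 1977 ± 317 CPM (SD, n = 2 each), a log2 change of 4.14 (SE 0.32, adjusted p = 0.0227). Spp1 rose by 6.47 (SE 0.64, adjusted p = 0.0428), to 836.5 ± 437 CPM, and Ctsl, a lysosomal protease, by 3.92 (SE 0.30, adjusted p = 0.0227). Arg1, the arginine-degrading enzyme of alternatively activated macrophages, rose by 3.60, Adam8, a membrane protease, by 2.64, and Abca1, a cholesterol exporter, by 2.27 (adjusted p = 0.0428 for each). Emp1 (3.61), Pde4d, which degrades cyclic AMP (3.15), and Ube2c (2.92) rose as well. Il1rn, the antagonist of the interleukin-1 receptor (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494), fell by 2.99 (SE 0.25, adjusted p = 0.0263), and Ly6i, a surface protein of the Ly6 family, by 4.43 (SE 0.56, adjusted p = 0.0428). Itgax, the integrin subunit CD11c, fell by 2.43. Phf11b (-2.27), Sema4d, a semaphorin (-2.09), Fgr, a kinase of the Src family (-1.95), Mbp (-1.78), Grk3 (-1.75) and Stk10 (-1.56) were the other large falls.

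By list in monocyte-derived cells at 72 h, 3 of 16 lipid-associated genes rose and 1 fell, or 12 and 2 when adjusted over the list alone (median 1.73; camera, adjusted p = 4.35e-20; adjusted p = 0.279 with an estimated correlation). Among interferon response genes 0 passed over all genes (edgeR), and 18 fell when adjusted over the list alone (median -1.93, adjusted p = 1.62e-24; adjusted p = 0.279 with an estimated correlation). Irf7 was lower by 2.06 and Oasl2 by 1.51 (adjusted p = 0.0519 for each). Of the cell cycle genes 1 rose and 11 rose when adjusted over the list alone (median 1.98, adjusted p = 8.49e-17; adjusted p = 0.366 with an estimated correlation). Iron and haem handling had a median of 0.93, with 7 members higher when adjusted over the list alone (adjusted p = 7.79e-06; adjusted p = 0.279 with an estimated correlation). Ncoa4, which carries ferritin to breakdown, was at 1.64 (adjusted p = 0.0535). Kupffer identity (0.75, preset adjusted p = 0.0271) and uptake (0.57, 0.00992) were higher, and monocyte genes (-0.86, 0.000996), MHC class II (-0.61, 0.0048) and cholesterol synthesis (-0.36, 0.0371) lower. For these 5, in that order, adjusted p = 0.656, 0.639, 0.639, 0.639 and 0.656 with an estimated correlation. Alternative activation (0.51, preset adjusted p = 0.0599), the inflammatory list (-0.57, 0.745), matrix enzymes (median -0.39 but mean 0.68, 0.352), glycolysis (0.35, 0.0633) and early stress (-0.22, 0.405) did not pass. Nor did hepatocyte (-0.30, 0.142), B cell (0.28, 0.94), neutrophil (1.69, 0.111) and endothelial (-0.41, 0.387) transcripts or peritoneal genes (-1.91, 0.111). With replicate number as a block, alternative activation (0.49, preset adjusted p = 0.0252) and hepatocyte transcripts (-0.57, 0.0463) passed.

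Of 11381 genes tested in monocyte-derived cells at 72 h, 33 changed (13 rose, 20 fell; edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 617 (256 rose, 361 fell), and edgeR 541 with replicate number as a block (225 rose, 316 fell, all 33 among them). With doublets kept the count was 4, and at Leiden resolution 2 it was 0 (edgeR; 1346 genes at an unadjusted p under 0.05). The count was 1 without control replicate 2, 3 and 6 without the 72 h replicates 1 and 2, 1 without the 96 h replicate 1 and 53 without control replicate 3. Of the 18 named genes that passed, 0, 3, 4, 1 and 18 kept their call without those libraries, and 17 and 13 without control replicate 1 and the 96 h replicate 2. Without control replicate 2, Kupffer identity (0.26), monocyte genes (-0.33) and uptake (-0.00633) lost their calls. Without the 72 h replicate 1, Kupffer identity (0.33), monocyte genes (-0.59), MHC class II (-0.42) and cholesterol synthesis (-0.17) lost theirs. The class mixes clusters unevenly. A cluster of classical monocytes held 28 and 27 of the cells of control replicates 1 and 2. A cluster led by Pf4, Trem2, Gpnmb and Ctsd held 3 and 1 in control, 1083 and 59 at 72 h and 1766 and 47 at 96 h. Spp1, Fabp5 and Gpnmb, with Trem2, Cd9, Apoe, Mmp12, Cd63 and Lgals3 of the same list, are among the markers that name the macrophage-like clusters. Arg1 is another of these markers. Of the 21 macrophage-like cells of control replicate 1, 17 lay in a cluster led by Cd207, C1qb, C1qa and C1qc, whose mean fold was higher for the markers of nonclassical monocytes (1.08) than for those of its name (0.842) and which held 534 of the 1884 of the 72 h replicate 1 and 753 of the 2829 of the 96 h replicate 1. In the macrophage-like clusters alone, with 1 control capture assumed to vary like the ConA libraries, the median of the lipid-associated list was 1.85, of interferon response -0.69 and of cell cycle 0.14, without a call for the last. Ly6i (8.82) and Il1rn (2.63) were higher in ConA there, monocyte genes were higher (2.35), and Kupffer identity (-0.20) and uptake (-0.20) lower. In the classical monocyte clusters alone, the first 3 medians were 0.56, -2.13 and 5.30, Kupffer identity was at -0.12 and MHC class II at 0.34. They include a cluster with Ly6c2, Prtn3, Elane, Ctsg and Mpo among its leading genes. It held 0 cells in control, 12 and 8 at 72 h and 40 and 14 at 96 h. Another, led by F13a1 and Vcan, held 0 in control, 21 and 3 at 72 h and 47 and 0 at 96 h. How much these clusters add to the cell cycle medians was not tested.

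At 96 h monocyte-derived cells again carried more transcripts of lipid-associated macrophage genes than control and fewer of interferon response genes. Spp1 rose by 6.60 (SE 0.64, adjusted p = 0.0208), to 920.0 CPM, Fabp5 by 4.18 (SE 0.32, adjusted p = 0.0128) and Ctsl by 4.03 (SE 0.31, adjusted p = 0.0128). Gpnmb, a membrane glycoprotein of lipid-laden macrophages, rose by 5.18 (SE 0.74, adjusted p = 0.0336), to 1228 ± 715 CPM from 31.8, and Ctsd, a lysosomal protease, by 3.83 (SE 0.49, adjusted p = 0.0301). Atp6v0d2, a subunit of the lysosomal proton pump, was at least 57.6-fold higher (8513 UMIs against 0 in control, floor of 3 counts over the group). Folr2, a folate receptor of resident macrophages, had a ratio of 109 (95% counting interval 19.6 to 4310, 1 control UMI). Syngr1 had one of 78.8 (21.8 to 651, 2 control UMIs). Such values pool the UMIs of a group, of which the 96 h replicate 1 held 54686543 and the 96 h replicate 2 held 3114643. Ly6i fell by 5.46, Il1rn by 3.50 (SE 0.26, adjusted p = 0.0128), Bcl2, which blocks apoptosis, by 2.68, and Itgax by 3.06. Stap1 (-2.68), Ifi213 (-2.63) and Zfyve9 (-2.50) fell too. Of 22 interferon response genes 5 fell and 21 fell when adjusted over the list alone (median -2.04; camera, adjusted p = 9.26e-22; adjusted p = 0.304 with an estimated correlation). They include Gbp2, a guanylate-binding protein (-3.07, adjusted p = 0.0478), Ifit2 (-2.83, adjusted p = 0.0436), Irf7 (-2.01) and Oasl2 (-1.53).

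Of the 16 lipid-associated genes at 96 h, 8 rose and 1 fell, or 13 and 2 when adjusted over the list alone (median 2.23; camera, adjusted p = 7.98e-21; adjusted p = 0.304 with an estimated correlation). Iron and haem handling had 2 members that rose and 9 when adjusted over the list alone (median 1.13, adjusted p = 3.64e-06; adjusted p = 0.304 with an estimated correlation). Ftl1, the ferritin light chain, rose by 2.20 and Ncoa4 by 1.75. In the cell cycle list 2 rose and 13 rose when adjusted over the list alone (median 2.27, adjusted p = 9.18e-19; adjusted p = 0.317 with an estimated correlation). Ube2c rose by 3.35, and Ccna2, a cyclin, had a ratio of 28.4 (5.08 to 1121, 1 control UMI). Uptake had a median of 0.66 (preset adjusted p = 0.00471), with Abca1 (2.32) and Stab1, a scavenger receptor (2.58), both of which rose. Kupffer identity (0.62, 0.0175) and glycolysis (0.81, 0.00152) were higher, and monocyte genes (-1.04, 0.00111), MHC class II (-0.95, 0.000414), cholesterol synthesis (-0.58, 0.0175) and hepatocyte transcripts (-1.12, 0.0149) lower. For these lists and uptake, adjusted p = 0.577 with an estimated correlation. Neutrophil transcripts had a median of 4.29, or 3.11 with Mmp9 at its bound (preset adjusted p = 0.00712; adjusted p = 0.432 with an estimated correlation), and S100a8 rose by 5.77. Arg1 rose by 3.27 and Adam8 by 2.61, while their lists did not pass.

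Of 11381 genes tested in monocyte-derived cells, 151 changed at 96 h (58 rose, 93 fell; edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 956 (443 rose, 513 fell), and edgeR 834 with replicate number as a block (363 rose, 471 fell, all 151 among them). With doublets kept the count was 7, and at Leiden resolution 2 it was 10. The count was 8 without control replicate 2, 0 without the 96 h replicate 1 (edgeR; 1398 genes at an unadjusted p under 0.05, against 2232 with all libraries) and 25 without the 96 h replicate 2. Of the 28 named genes that passed, 1 (Il1rn), 0 and 14 kept their call without those libraries, 26 and 27 without control replicates 1 and 3, and 28 and 28 without the 72 h replicates. Kupffer identity, monocyte genes and uptake lost their calls without control replicate 2 (0.12, -0.50 and 0.29) and without the 96 h replicate 1 (-0.42, -0.51 and 0.44). Cholesterol synthesis (-0.41) and glycolysis (0.49) lost theirs without the 96 h replicate 1, and hepatocyte transcripts without control replicate 2 (0.25). In macrophage-like clusters alone the medians were 2.13 for the lipid-associated list, -0.71 for interferon response and 0.07 for cell cycle, the last without a call; Ly6i (8.20), Il1rn (2.26), Gbp2 (0.30), monocyte genes (2.29) and hepatocyte transcripts (0.68) were higher there in ConA, and Kupffer identity (-0.25) lower. In classical monocyte clusters alone, which include the clusters without control cells, the first 3 medians were 0.41, without a call, -2.59 and 6.53. Kupffer identity was at -0.0272 there and monocyte genes at 0.0146.

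Between 96 h and 72 h no gene changed in monocyte-derived cells in edgeR (0 calls of 11381, 117 at an unadjusted p under 0.05), and DESeq2 called 1. Ccl7 (-2.26) and Ccl2 (-1.998), chemokines that attract monocytes, were lower at 96 h (adjusted p = 1 for both). The inflammatory list that holds them had a median of -0.26 (camera, adjusted p = 0.00268; adjusted p = 0.782 with an estimated correlation). Without the 72 h replicate 2 the median was 0.12, and without the 96 h replicate 1 it was -0.15, without a call in either case.

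**Figure D3:**
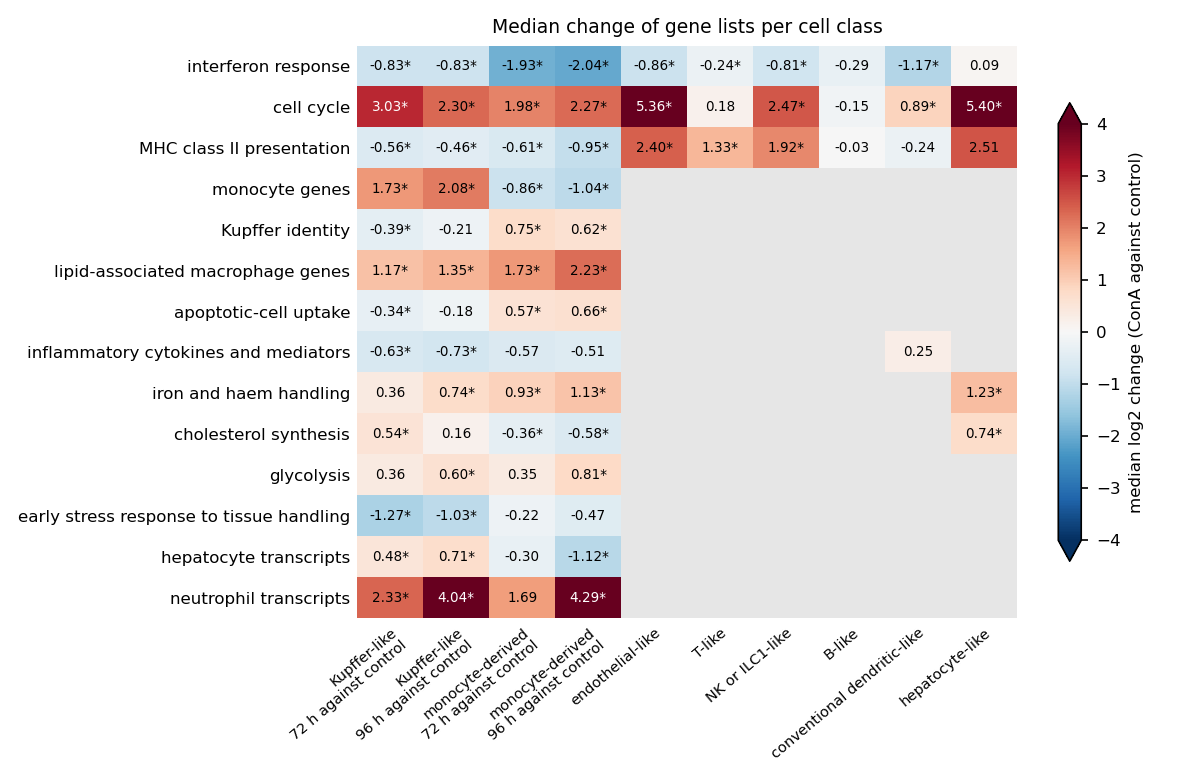
Median log2 change of 14 gene lists (vertical axis) in 10 comparisons of a cell class in ConA with control (horizontal axis), coloured from blue (lower) to red (higher in ConA), with an asterisk for a preset adjusted p under 0.05 and grey for lists not tested. Interferon response lies at -0.83 in Kupffer-like cells at both times, and cell cycle at 3.03 and 2.30.

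Endothelial-like cells were compared between ConA (n = 4) and control (n = 2) as part of the tissue around the macrophages. They carried far more transcripts of cell division after ConA and fewer of the factors that sinusoidal cells make. Top2a, the topoisomerase that untangles replicated DNA (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), rose from 0.298 ± 0.421 to 159 ± 81.6 CPM, a log2 change of 8.15 (SE 0.73, adjusted p = 0.000201). Mki67 rose by 8.12 (SE 0.79, adjusted p = 0.000236). Prc1, a protein of the dividing spindle, had a ratio of 319 (95% counting interval 109 to 1550, 3 control UMIs). Of the 20 cell cycle genes 18 rose, 19 when adjusted over the list alone (median 5.36; camera, adjusted p = 1.77e-53; adjusted p = 0.0557 with an estimated correlation), Ccna2 at least 127-fold and Ccnb1 at least 72.3-fold. Cd34, a marker of capillary endothelium, rose by 3.08 (SE 0.28, adjusted p = 0.000201) and Kit, the receptor of stem cell factor, fell by 1.03. Their list of capillary genes passed by the preset test (median 0.49, preset adjusted p = 0.0272; adjusted p = 0.209 with an estimated correlation). Of 9 angiocrine factors, Wnt2, which sets the metabolic zones of hepatocytes, fell by 0.99, Bmp2, which controls iron through hepcidin, by 0.79 and Cxcl12, a chemokine, by 1.92. Their list was lower (median -0.63, adjusted p = 0.00287; adjusted p = 0.0996 with an estimated correlation). Of 12 genes of sinusoidal identity, Dnase1l3, a secreted nuclease, fell by 1.13 and Cd209b, a lectin, by 2.11 (median -0.46, adjusted p = 0.00287; adjusted p = 0.309 with an estimated correlation). Of 22 interferon response genes 8 fell, 15 when adjusted over the list alone (median -0.86, adjusted p = 5.78e-10; adjusted p = 0.117 with an estimated correlation), among them Oasl2 (-1.31) and Ifit3 (-1.69). MHC class II had a median of 2.40 (adjusted p = 0.00287; adjusted p = 0.315 with an estimated correlation), with H2-Aa, a chain of the antigen-presenting molecule, at 2.82. Its UMIs were 0.0193%, 0.00459%, 0.0421% and 0.00545% of all UMIs in endothelial-like cells of the 4 ConA libraries (9974 to 17210 UMIs per cell). In T-like cells of the same libraries they were 0.0260%, 0.0157%, 0.0540% and 0.00804% (5321 to 11260 UMIs per cell). Per cell, H2-Aa stood at 0.434, 0.132, 0.559 and 0.125 UMIs in endothelial-like cells of these libraries. T-like cells held 0.303, 0.213, 0.332 and 0.0274. The percentages compare cells of unlike depth and cannot decide on free RNA, so the list is not read as expression. Chchd10 (-2.78), Rnd3 (-2.24) and Car3, a carbonic anhydrase that hepatocytes express abundantly (-2.18), were among the largest falls, and the rises include Hist1h2ap, a histone of a family with similar sequences (8.01).

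Of 12361 genes tested in endothelial-like cells, 933 changed (699 rose, 234 fell; edgeR quasi-likelihood, Benjamini-Hochberg), and 509 without control replicate 2, 464 without the 72 h replicate 1 and 592 without the 96 h replicate 1. Without control replicate 2, Bmp2, Cd209b, Dnase1l3 and H2-Aa and the capillary list (0.53) lost their calls; H2-Aa also lost it without control replicate 3, and Dnase1l3 without either 72 h replicate. Most control cells lay in a cluster led by Stab2 (682 and 26 cells in control replicates 1 and 2, 10, 0, 33 and 1 in ConA) and most ConA cells in another (134 and 7, 581, 23, 1323 and 26).

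T-like cells, the cells that ConA activates, carried more effector transcripts in ConA than in control. Gzma, a killer protease (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), rose from 28.2 ± 19.0 CPM (SD, n = 2) to 699 ± 167 CPM (SD, n = 4), a log2 change of 4.48 (SE 0.42, adjusted p = 0.0151). The chemokines Ccl4 and Ccl5 rose by 2.87 and 1.99, and S100a4, a calcium-binding protein of memory cells, by 2.27. Zeb2, a transcription factor of effector cells, rose by 2.09 and Ctla4, an inhibitory receptor, by 1.51, while Dusp10, a phosphatase that dampens stress kinases, fell by 1.21. Of 13 effector genes 3 rose, 9 rose and 1 fell when adjusted over the list alone (median 1.99; camera, adjusted p = 1.62e-16; adjusted p = 0.0509 with an estimated correlation). Activation and inhibitory receptors had a median of 0.24 (adjusted p = 0.000383; adjusted p = 0.0509 with an estimated correlation). Interferon response had one of -0.24 (adjusted p = 0.000383; adjusted p = 0.242 with an estimated correlation) and MHC class II one of 1.34 (adjusted p = 0.029; adjusted p = 0.491 with an estimated correlation). T-like cells of ConA held 0.767 to 2.87 UMIs of the latter list per cell, close to the 0.790 to 4.20 of endothelial-like cells, which is not read as expression. Cell cycle (0.18, preset adjusted p = 0.34) did not pass. Of 10126 genes 23 changed (20 rose, 3 fell; edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 129 (80 rose, 49 fell), and edgeR 76 with replicate number as a block (44 rose, 32 fell). With doublets kept 8 genes changed. The count was 0 without control replicate 2 (edgeR; 720 genes at an unadjusted p under 0.05) and 4 without the 96 h replicate 2, and 0 and 3 of the 7 named genes kept their call there. Ccl4 lost its call without control replicate 1, Dusp10 and Ccl5 lost theirs without the 72 h replicates 1 and 2, and 5 of 7 genes kept it without the 96 h replicate 1. MHC class II lost its call without control replicate 2 (0.84), the 72 h replicate 1 (1.30) and the 96 h replicate 1 (0.60).

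NK or ILC1-like cells, innate killer and helper lymphocytes, carried more cell cycle transcripts and less Xcl1 in ConA. Xcl1, a chemokine that attracts dendritic cells (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), fell from 1086 ± 256 CPM (SD, n = 2) to 239 ± 22.7 CPM (SD, n = 4), a log2 change of -2.18 (SE 0.20, adjusted p = 0.00476). Cd200r2 (-2.84, SE 0.31, adjusted p = 0.00909), Gzmc, a granzyme (-3.19), and Nmnat2, an enzyme of NAD synthesis (-2.26), fell. Cenpf, a kinetochore protein (4.31), Ube2c (4.18), Lgals3, a galectin (3.996), and Mki67 (3.41) rose. T-like cells of the ConA libraries held 0.589 to 1.40 Lgals3 UMIs per cell, so a part from free RNA is open for Lgals3. Gzmk, another granzyme, had a ratio of 21.9 (95% counting interval 3.85 to 875, 1 control UMI), and Ect2, needed for cell division, of 15.2 (5.13 to 74.3, 3 control UMIs). Of their 20 cell cycle genes 6 rose, 17 when adjusted over the list alone (median 2.47; camera, adjusted p = 2.08e-29; adjusted p = 0.104 with an estimated correlation). Interferon response had a median of -0.81 (adjusted p = 3.45e-05; adjusted p = 0.118 with an estimated correlation). MHC class II had one of 1.92 (adjusted p = 0.00305; adjusted p = 0.247 with an estimated correlation), at 0.522 to 4.86 UMIs per cell in ConA against 0.767 to 2.87 in T-like cells, which is not read as expression, and activation receptors one of -0.70 (adjusted p = 0.0257; adjusted p = 0.151 with an estimated correlation). Effector genes (median -0.24, mean 0.11, preset adjusted p = 0.217) did not pass. Of 7972 genes 66 changed (34 rose, 32 fell; edgeR quasi-likelihood, Benjamini-Hochberg) and 186 with DESeq2 (110 rose, 76 fell), but 3 at Leiden resolution 2. With at least 50 cells 824 changed, between 1 control capture and 2 ConA libraries. The count was 10 without control replicate 2, 19 without the 72 h replicate 1, 255 without the 72 h replicate 2 and 102 without the 96 h replicate 2. Of the 10 named genes 3, 6, 10 and 10 kept their call there, and 8 without the 96 h replicate 1. The activation list lost its call without control replicate 1 (-0.44) and without control replicate 2 (-0.29).

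B-like cells showed no called gene (0 of 7756 in edgeR, 419 at an unadjusted p under 0.05; 5 in DESeq2). Their interferon response (-0.29), MHC class II (-0.03) and cell cycle (-0.15) lists did not pass (preset adjusted p = 0.422 for each). The count was 2 without control replicate 2, 6 without the 72 h replicate 2 and 1 without the 96 h replicate 1. Conventional dendritic-like cells, which present antigen to T cells, had 1 control capture with enough cells (80.5 cells on average), which was assumed to vary like the ConA libraries, and no gene of 10269 was called in edgeR (1258 at an unadjusted p under 0.05; 206 in DESeq2), with 3 called without the 72 h replicate 2 and 2 without the 96 h replicate 1. Interferon response was lower there by a median of -1.17 (camera, adjusted p = 3.41e-09; adjusted p = 0.128 with an estimated correlation), with Ifit2 at -2.01 (adjusted p = 0.162). Cell cycle was higher by 0.89 (adjusted p = 5.6e-11; adjusted p = 0.227 with an estimated correlation), with Cenpf at 2.09 (adjusted p = 0.0928). MHC class II (-0.24) and the inflammatory list (0.25) did not pass (preset adjusted p = 0.195 for both). These values set the ConA libraries against that 1 capture, which cannot be told apart from its group. With at least 10 cells, a minimum chosen after seeing the data that admits the other control capture (18 cells), the median of interferon response was -1.38 and of cell cycle 0.51, and both kept their call by the preset test. The planned test could not be run in neutrophil-like cells, where no control capture held 20 cells, or in stellate-like cells, where 1 control capture and 1 ConA library did. The same minimum gave 0 called genes in neutrophil-like cells (edgeR, 1974 at an unadjusted p under 0.05) and 162 in stellate-like cells, there with 1 control capture and 2 ConA libraries, so that these calls hold for that capture alone.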

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

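The tests of free RNA as the whole cause, of 11 mitotic genes and of the UMIs outside the highest genes were chosen only after the result was seen; the other tests were fixed before the values they measure were seen.

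Interferon response genes were lower in ConA in Kupffer-like and monocyte-derived cells at both times. The tables argue against a difference between replicate numbers as the cause. The list's median log2 difference was -0.66 or lower within both numbers in both classes. The labels give the same preparation for all libraries, and a difference in handling between control and ConA within a number was not tested. Such a difference stays open. The early stress response to tissue handling had a median of -1.28 at 72 h and -1.03 at 96 h in Kupffer-like cells. In monocyte-derived cells it was -0.22 and -0.47. The tables also argue against a few genes taking most of the counts. Outside the 20 highest genes of any library, the lowest ConA library differed from the highest control capture by -0.0777 (log2 share of UMIs). Free RNA remains open: hepatocyte-like droplets of control held up to 0.2501 of the fall per Kupffer-like cell. With the level of B-like cells taken off in control alone, Kupffer-like cells of the lowest control capture held 1.32 times the level of the highest ConA library, under the 1.5 set to exclude it. A biological fall of interferon signalling after ConA may stand beside it, as a hypothesis.

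Cell cycle genes were higher in Kupffer-like cells of ConA. Against free RNA as the whole cause, the 11 mitotic genes of the lowest ConA library stood at 2.73 times the highest control capture after the level per B-like cell was taken off. In control replicates 1 and 2, B-like cells held 2.52 and 0.101 UMIs of these genes per cell, and Kupffer-like cells 1.07 and 0.621. The level of B-like cells is thus not free RNA alone in replicate 1, and it serves as an upper limit of free RNA. By the share of other-cell UMIs, cells with mitotic UMIs stood at 0.727 of cells of the same cluster without them in ConA. In control replicates 1 and 2 the ratio was 0.897 and 0.810. This cannot decide on a cycling cell of another class in the same droplet. Cells with mitotic UMIs held a median of 16750 UMIs against 8783 in ConA. The other-cell lists cover hepatocytes, T, B, neutrophil, endothelial and stellate cells alone, and not monocyte-derived, dendritic or NK cells. Free RNA as a part stays open, since B-like cells of ConA held up to 0.620 of the cell cycle UMIs of Kupffer-like cells, as does a cycling cell of another class by all cell cycle genes (0.983 over ConA, but 0.541 and 1.91 in the replicates 1 of 72 h and 96 h). That Kupffer-like cells divide after ConA may be the biological reading, as a hypothesis.

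Lipid-associated macrophage genes were higher in monocyte-derived cells of ConA. Trem2, Gpnmb, Spp1, Cd9, Apoe, Mmp12, Fabp5, Cd63 and Lgals3 of this list are also markers that name the macrophage-like clusters. The rise of the list is therefore not independent of the naming. Free RNA is argued against, since T-like cells of the same libraries held at most 0.0300 of the rise per monocyte-derived cell. The mix of monocytes and macrophages in the class stays open: in classical monocyte clusters alone the lower of the medians was 0.412, between the bounds of 0.3 and 0.5, and in macrophage-like clusters alone the medians were 1.85 and 2.13, but with 1 control capture, of whose cells most lay in another cluster than most ConA cells did. A change within cells after ConA may add to the mix, as a hypothesis.

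In Kupffer-like cells these lists differed between 96 h and 72 h by the preset test: Kupffer identity (median 0.16), lipid-associated genes (0.34), uptake (0.25), cell cycle (-0.80), iron and haem handling (0.38), cholesterol synthesis (-0.33), glycolysis (0.23), hepatocyte (0.23), neutrophil (1.44), endothelial (0.93) and stellate (0.84) transcripts. With an estimated correlation their adjusted p = 0.265 to 0.667, and glycolysis lost its call with replicate number as a block (0.18). Of the lists with a value, 5, 5, 4 and 9 kept the call without the 72 h replicates 1 and 2 and the 96 h replicates 1 and 2, cell cycle and neutrophil transcripts each time. In monocyte-derived cells the lists were lipid-associated genes (0.28), the inflammatory list (-0.26), MHC class II (-0.16), cell cycle (0.33), glycolysis (0.20) and hepatocyte (-0.91), neutrophil (1.59) and endothelial (1.10) transcripts, with adjusted p = 0.684 to 0.796 with an estimated correlation, and hepatocyte transcripts lost their call with the block (-0.36). Of these 8, 7, 3, 1 and 6 kept the call without the same libraries.

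Shares of all cells in ConA minus control moved in opposite ways within replicate numbers 1 and 2, a difference that was not tested: Kupffer-like -3.32 and 0.208 points, cholangiocyte-like -1.33 and 0.354, mesothelial-like -0.176 and 0.143, stellate-like -0.804 and 0.0942 (with doublets kept, stellate-like -0.251 and 0.259 and cholangiocyte-like -1.07 and 0.341). Haemoglobin took 39.9% of the UMIs of the 96 h replicate 2, and 2556 of its barcodes held over 10% haemoglobin. Some unnamed, basophil-like and erythroid-like clusters had few or no cells in control. In the 4 ConA libraries they held 106 cells (led by Thbs1 and Trps1), 99 (Ckap2l and Sgo2a), 66 (Adgb and Adgrl3) and 103 (Thbs1 and Pparg). The rest of them held 81 (Adgrl3 and Rasgef1b), 71 basophil-like, 88 (Mpo, Ctsg and Prtn3) and 81 erythroid-like cells. Further clusters without control cells, most of them named, are not listed here.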

How the results depend on the processing

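Control replicates 1 and 3 as separate libraries, control replicate 2 as the sole control library, the Kupffer-like cluster of full UMI count, classical monocyte clusters alone, at least 10 cells, and all values of hepatocyte-like cells were chosen only after the result was seen. Of 113 changes of a named gene in 1 comparison past the threshold, 108 kept their direction in every setting run; of 1869 values 1328 kept the call, 536 lost it and 5 reversed. All 113 kept the call with no low-count filter, with the replicate block and with control replicates 1 and 3 apart, 110 with DESeq2, 101 with the strict cell filter, 63 with doublets kept, 58 at resolution 2, and 12 of 112 with control replicate 2 alone. It was kept by 32 without control replicate 2 and 40 of 111 without the 96 h replicate 1. Of 83 list tests past the threshold, each 1 list in 1 class and comparison, 60 kept their direction in every setting; of 1309 values 1137 kept the call, 126 lost it and 46 reversed. The number of cells limits some classes: neutrophil-like cells in control and stellate-like cells in both groups were too few for the planned test. With doublets kept the 4 ConA libraries held 52, 25, 97 and 29 stellate-like cells, and with 1 control capture 0 genes were called (edgeR; 596 at an unadjusted p under 0.05). With at least 50 cells no test of monocyte-derived cells with control could be had. A left-out library or a minimum of cells can leave 1 sample in a group (NK or ILC1-like with at least 50 cells, dendritic-like in most settings), which is then assumed to vary like the other groups. Except where a setting has fewer samples, cells or genes by construction, the cause was not tested.

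Counts of changed genes are given for Kupffer-like cells at 72 h (37) and 96 h (10), monocyte-derived cells at 72 h (33) and 96 h (151), and endothelial-like (933), T-like (23), NK or ILC1-like (66), B-like (0), conventional dendritic-like (0) and hepatocyte-like cells (592), where they moved by over 1.5 times. With DESeq2 they were 195 and 137, 617 and 956, T-like 129, NK or ILC1-like 186, B-like 5, dendritic-like 206 and hepatocyte-like 1161, and 1 gene for monocyte-derived cells at 96 h against 72 h. With no low-count filter they were 586 and 501, 1015 and 1379, endothelial-like 1764, T-like 331, NK or ILC1-like 641, B-like 171 and dendritic-like 115, and 63 and 96 for 96 h against 72 h in Kupffer-like and monocyte-derived cells. With the strict cell filter they were 22 and 1 in Kupffer-like cells. With predicted doublets kept they were 142 and 61, 4 and 7, T-like 8 and hepatocyte-like 353. At Leiden resolution 2 they were 149 and 57, 0 (edgeR; 1346 at an unadjusted p under 0.05) and 10, NK or ILC1-like 3, dendritic-like 3 and hepatocyte-like 332. With at least 50 cells they were 3 in Kupffer-like cells at 96 h, NK or ILC1-like 824 and B-like 59, and with at least 10 cells dendritic-like 128. With the replicate block they were 240 and 178, 541 and 834, T-like 76, NK or ILC1-like 145, B-like 9, dendritic-like 33 and hepatocyte-like 2394. With control replicates 1 and 3 as separate libraries they were 382 and 211, 659 and 1129, endothelial-like 2538, T-like 246, NK or ILC1-like 684, B-like 3, dendritic-like 956 and hepatocyte-like 1976. With control replicate 2 as the sole control library they were 0 and 0, 0 (edgeR; 885, 769 and 2225 at an unadjusted p under 0.05) and 1, endothelial-like 21, T-like 3, NK or ILC1-like 7, B-like 11 and hepatocyte-like 250. In the Kupffer-like cluster of full UMI count 134 genes changed at 72 h, in macrophage-like clusters 80 at 72 h, and in classical monocyte clusters 94 and 565. Without each library in turn the counts ranged from 5 to 61 and 0 to 57 in Kupffer-like cells, 1 to 53 and 0 to 174 in monocyte-derived, 464 to 1134 in endothelial-like, 0 to 24 in T-like, 10 to 255 in NK or ILC1-like, 0 to 6 in B-like, 0 to 3 in dendritic-like and 244 to 740 in hepatocyte-like cells, and stayed at 0 for 96 h against 72 h in both macrophage classes. The block values of NK or ILC1-like and B-like cells stand here alone. The lowest correlation of their replicate numbers between groups was -0.0119 and 0.0962. In endothelial-like cells it was 0.0921, and each lay under the 0.116 of Kupffer-like cells.

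The Kupffer-like share of all cells (ConA minus control, -1.56 points) was -25.5 points of leukocytes, -57.8 of monocytes and macrophages and 3.39 with control replicate 2 as the sole control library; without each library it ranged from -6.50 to -0.477. The monocyte-derived share (17.2 points) was 57.8 points of monocytes and macrophages and ranged from 11.6 to 22.3 without each library.

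Values that reversed in macrophage-like clusters alone were Ly6i (8.82 at 72 h, 8.20 at 96 h), Il1rn (2.63, 2.26) and Gbp2 (0.30 at 96 h). Medians of lists in monocyte-derived cells that reversed there were Kupffer identity (-0.20, -0.25), monocyte genes (2.35, 2.29), uptake (-0.20 at 72 h), hepatocyte transcripts (0.68 at 96 h) and, at 96 h against 72 h, MHC class II (0.12) and cell cycle (-0.20). In classical monocyte clusters they were Kupffer identity (-0.12, -0.0272), MHC class II (0.34 at 72 h), monocyte genes (0.0146 at 96 h) and lipid-associated genes at 96 h against 72 h (-0.47). Hepatocyte transcripts in Kupffer-like cells at 72 h, 96 h and 96 h against 72 h were -0.998, -0.74 and -0.29 with the strict filter and -0.43, -0.46 and -0.34 in the cluster of full UMI count. At 96 h and 96 h against 72 h they were -0.57 and -0.97 with doublets kept and -0.64 and -0.80 at resolution 2. They were -0.22 at 72 h with control replicate 2 as the sole control library and -0.36 at 96 h against 72 h with at least 50 cells, where iron and haem handling was at -0.0857. Stellate transcripts in Kupffer-like cells at 96 h were -0.0687 with control replicates 1 and 3 apart and -0.10 in the cluster of full UMI count.

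Without each library in turn, medians of lists that reversed ranged as follows, with the library that gave the reversal. In Kupffer-like cells against control they were the inflammatory list at 72 h, from -1.12 to 0.0505 (72 h replicate 1), hepatocyte transcripts at 72 h, from -0.65 (72 h replicate 2) to 2.21, and stellate transcripts at 96 h, from -0.12 (control replicate 2) to 2.51. At 96 h against 72 h they were iron and haem handling, from -0.0857 (96 h replicate 2) to 0.42, and cholesterol synthesis, from -1.01 to 0.23 (72 h replicate 2; 0.0352 without the 96 h replicate 1). There, hepatocyte transcripts ranged from -0.52 (72 h replicate 1; -0.36 without the 96 h replicate 2) to 1.61 and endothelial transcripts from -1.31 (96 h replicate 1) to 1.89. In monocyte-derived cells against control they were uptake at 72 h, from -0.00633 (control replicate 2) to 0.70, Kupffer identity at 96 h, from -0.42 (96 h replicate 1) to 1.16, and hepatocyte transcripts at 96 h, from -1.18 to 0.25 (control replicate 2). At 96 h against 72 h, without the 96 h replicate 1, they were lipid-associated genes, from -0.0724 to 0.56, glycolysis, from -0.00896 to 0.35, and neutrophil and endothelial transcripts, from -0.0783 to 3.09 and from -1.35 to 2.75. Without the 72 h replicate 2 they were the inflammatory list, from -0.69 to 0.12, and hepatocyte transcripts, from -1.76 to 0.90.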

Other observations

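The comparison of hepatocyte-like cells and the values of rare classes were chosen only after the data were seen. Hepatocyte-like cells carried far more transcripts of cell division in ConA (n = 4) than in control (n = 2). Cdkn3, a phosphatase of cyclin-dependent kinases, rose from 0.192 to 113 CPM, a log2 change of 9.19 (SE 0.45, adjusted p = 0.000160), Ccnb2, a mitotic cyclin, by 9.09, Birc5 by 8.91 and Lockd, a transcript beside a cell cycle inhibitor, by 8.95. Of 20 cell cycle genes 17 rose, 20 when adjusted over the list alone (median 5.40; camera, adjusted p = 6.34e-78; adjusted p = 0.00755 with an estimated correlation). Iron and haem handling was higher by a median of 1.23 (adjusted p = 0.000782; adjusted p = 0.204 with an estimated correlation), with Tfrc, the receptor for transferrin, which rose by 2.73 (adjusted p = 0.0111). Cholesterol synthesis was higher by 0.74 (adjusted p = 0.00778; adjusted p = 0.479 with an estimated correlation). Interferon response did not pass (median 0.09, mean 0.01, preset adjusted p = 0.471); within it Cxcl9, a chemokine for T cells, rose by 1.57 and Ifit1 fell by 2.37 (adjusted p = 0.0322 for both). MHC class II was at 2.51 (preset adjusted p = 0.0981) and passed with replicate number as a block (2.14, 0.000973), at 0.108 to 2.56 UMIs per cell in ConA, in each library under the 0.767 to 2.87 of T-like cells, which is not read as expression. The largest falls were Mup18 (-6.37), Mup17 (-5.17), Mup11 (-4.68) and Mup16 (-4.56), major urinary proteins, a family of near-identical genes between which reads are shared, with a control SD as large as the mean.

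Of 12078 genes in hepatocyte-like cells 592 changed (404 rose, 188 fell; edgeR quasi-likelihood, Benjamini-Hochberg) and 2394 with replicate number as a block (1579 rose, 815 fell). The count was 353 with doublets kept and 332 at Leiden resolution 2, 264 without the 72 h replicate 1, 399 without the 96 h replicate 1 and 244 without the 96 h replicate 2. Of the 11 named genes 6, 7 and 6 kept their call there, 8 without control replicate 2 and 7 without the 72 h replicate 2. Nearly all cells of control and of ConA lay in different clusters, and those of control replicates 1 and 2 did as well.

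Immature neutrophil-like cells, led by Ngp, Camp and Ltf, numbered 0 in control, 19 and 8 at 72 h and 184 and 28 at 96 h. Basophil-like cells were 0% and 1.29% of leukocytes in control and 0.480%, 2.98%, 0% and 3.98% in ConA (72 h replicates 1 and 2, then 96 h; exact p = 0.467). With doublets kept, which restores such cells in the 96 h replicate 1, they were 0% and 0.0406% of all cells in control and 0.364%, 0.264%, 0.314% and 0.497% in ConA (exact p = 0.0667, the smallest that the 15 splits allow). Erythroid-like cells were 0.147% and 0.0111% of all cells in control and 0.604%, 1.68%, 0.722% and 7.40% in ConA (exact p = 0.4).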
